A study of Homo sapiens with 11 samples.

How the data were processed

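RNA from the human acute myeloid leukaemia line MV4-11 was hybridised to 11 Affymetrix arrays, 1 array per condition. The 8 knockdown arrays held every combination of shRNAs against RUNX1, RUNX2 and RUNX3, including a luciferase shRNA control (shLuc) without any of them. Per the labels' protocols, these cells were transduced and then kept with doxycycline at 3 µM for 24 hours. The 3 remaining arrays came from cells kept for 6 hours with DMSO, Chb-M' or Chb-50, each compound at 1 µM. Per the labels' protocols, biotinylated cDNA was made with the Affymetrix WT PLUS kit.

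The deposited values are log2 levels per transcript cluster, a group of probes read together for a transcribed locus. Per the submitters' processing notes, Affymetrix Expression Console 1.3.1, Transcriptome Analysis Console 1.0 and RMA were used, with no role or order given. The log2 scale was read from the values, which lay between 0.48 and 12.74 with array medians over the genes tested between 5.86 and 5.91. The genome build behind the probe annotation is not given in the sources used here. No detection p-values or probe intensities were used here, so signal over background is unknown and the number of arrays sets the precision.

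The table held 53617 transcript clusters, and all columns were mapped to a sample. In the platform annotation 23558 clusters had 1 gene symbol, 2155 had several and 27904 had none listed. Entrez identifiers of 22271 of the 1-symbol clusters were found in a RefSeq table for GRCh38.p14, and 3 symbols were updated from it. The 1-symbol clusters covered 22109 genes. For the 618 genes with more than 1 cluster, the cluster with the highest mean level was used. Genes whose highest level over the 11 arrays reached the median of all 1-symbol values, 3.80, were tested, which left 12147 genes, of which 10572 are protein-coding. RUNX1 is listed only together with LOC100506403 on a shared cluster, which is given under both names and is not among the genes tested.

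Effects of each shRNA were fitted with limma 3.58.1 in R 4.3.3 on the 8 knockdown arrays, with the presence of the 3 shRNAs as additive terms and 4 residual degrees of freedom. Every p-value of these fits is moderated by eBayes (3.19 prior degrees of freedom) and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. A further fit used the number of RUNX genes targeted, from 0 to 3, as a numeric term with 6 residual degrees of freedom. The labels give 1 sample per condition, so the spread in these fits comes from arrays of different conditions after the additive terms are removed, and it includes any interaction between shRNAs. Nothing in the labels says that the arrays came from separate transductions or days, so the p-values measure only the spread between these arrays, which may be technical.

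The compound arrays have no replicates. Differences between single arrays were counted at 2-fold (a log2 difference of 1) without a test. A pooled-spread limma fit on all 11 arrays, which assumes that the DMSO and compound arrays vary like the knockdown arrays, is given beside these counts, and its 95% intervals use 7.19 degrees of freedom. The RUNX levels were compared between the 4 arrays with and the 4 without each shRNA by an exact two-sided permutation test over the 70 assignments, whose smallest possible p is 0.0286. There were 9 such tests, adjusted together.

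Before the data were examined, 28 gene lists, the tests, the processing alternatives and the rule for naming genes were fixed, and 27 lists had at least 5 tested members. Results of 2 of these lists are not reported here, although adjustment over the lists includes them, and a few genes that the naming rule picked are left out. In the limma fits, lists were tested with camera at its preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. For differences of single arrays, a list's median is given with its percentile among 10000 random lists of the same size, matched on mean level in 20 bins. These percentiles describe the arrays compared and are not p-values, and the random lists were not matched on gene length. Old histone and other symbols were replaced by current ones before matching.

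The naming rule took RUNX1, RUNX2, RUNX3, CBFB, MDM2, CDKN1A, BCL11A and TRIM24 in every comparison. It added the 12 highest and 12 lowest genes of each compound comparison, the 10 highest and 10 lowest of the triple knockdown, and up to 8 called genes per direction in each limma fit, or the 5 genes of smallest p where none was called. The 2 largest rises and the 2 largest falls of each list completed it. Small RNAs, olfactory receptors, antisense and uncharacterised loci were counted but not named. The prefix for 5S ribosomal RNA copies was added to that exclusion after the data were seen. Genes named because at most 5 members of a list passed, or as further members of such a list, were chosen after their values were seen.

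Correlations across genes compare arrays, and genes are not independent replicates. Because both compounds share the DMSO array, unchanged arrays were simulated 100 times against a shared control with the residual spread of the knockdown arrays (median SD 0.111). Genomic span was the RefSeq gene length in GRCh38.p14, available for all 10572 protein-coding genes tested. The alternatives tried were other level filters, the mean over clusters, repeated quantile normalization, centring of each array, a mean-variance trend with robust eBayes, an adjusted p threshold of 0.1, other model terms, other fold thresholds and leaving out each array in turn. Tests of the interaction term of each pair of shRNAs, exact sign-flip tests over the 4 pairs of arrays that differ only in a given shRNA, exact permutation of list means, protein-coding genes alone and simulated differences between 2 arrays were chosen after seeing the data.

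The fits were tested on simulated data with 50 genes changed at each fold size among 12147. The RUNX1 comparison recovered 90% at 1.5-fold and 100% at 2-fold, the fit on the number of targets recovered 54% and 92%, and the pooled-spread test of Chb-M' recovered 12% and 86%. Outside the changed genes these fits called 10, 16 and 12 genes, and with no simulated change the RUNX1 comparison called 0. The simulated noise was normal with the moderated residual spread, so these shares may overstate the power of the real fits. In the real RUNX1 fit SPOPL did not pass at a log2 difference of 0.65 (limma adjusted p = 0.0755). A count of 0 there is therefore no evidence against changes of this size. For the random lists, all 27 lists shifted by 0.3 lay above the 97.5th percentile, and 1 unshifted list lay outside the range from 2.5 to 97.5. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.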

Results

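Transcript levels were measured on 11 arrays of MV4-11, an established acute myeloid leukaemia line that carries a KMT2A rearrangement. RUNX1, RUNX2 and RUNX3 encode DNA-binding transcription factors that pair with the shared partner CBFB. The series asked how expression genome-wide changes when these genes are knocked down or when cells meet alkylating PIP conjugates, and the title names joint regulation of the RUNX family. Of the 8 knockdown arrays, 4 carried each RUNX shRNA and 4 did not. The control arrays were shLuc for the knockdowns and DMSO for the compounds, and each condition had 1 array. Array medians over the genes tested lay between 5.86 and 5.91, and the number of arrays limits the precision.

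RUNX2 was lower on every array with its shRNA than on every array without it, and the RUNX3 and RUNX1 readings moved less cleanly. RUNX2 averaged 5.70 ± 0.107 (SD, n = 4) with and 6.14 ± 0.123 (SD, n = 4) without its shRNA, a log2 difference of -0.45, or 73.4% of the level (exact permutation p = 0.0286, the smallest possible; adjusted over the 9 tests, 0.257). RUNX3 averaged 7.74 ± 0.105 (SD, n = 4) with and 8.11 ± 0.291 (SD, n = 4) without its shRNA, a difference of -0.38 (exact permutation p = 0.0857; adjusted, 0.257). The array labelled shRUNX1 had a RUNX3 level of 7.70, inside the range of 7.65 to 7.88 on the arrays with the RUNX3 shRNA, although that shRNA is not on its label. The cluster listed for both RUNX1 and LOC100506403 averaged 4.09 ± 0.129 (SD, n = 4) with and 4.30 ± 0.109 (SD, n = 4) without the RUNX1 shRNA, a difference of -0.21 (exact permutation p = 0.0857; adjusted, 0.257). Its level was 4.12 on the array labelled shRUNX1, 4.03 on shRUNX1+shRUNX3 and 3.96 on the triple knockdown. The array labelled shRUNX1+shRUNX2 read 4.26, inside the range of 4.20 to 4.45 on the arrays without the RUNX1 shRNA. Against the array that differs only in the RUNX1 shRNA, the cluster was lower in all 4 pairs, by -0.18 on shRUNX1, -0.19 on shRUNX1+shRUNX2, -0.17 on shRUNX1+shRUNX3 and -0.29 on the triple knockdown (exact sign-flip permutation p = 0.125, the smallest possible with 4 pairs). It was also lower in all 4 pairs that differ only in the RUNX3 shRNA, by a mean of -0.17 against -0.21 for the RUNX1 shRNA, so the drop is not specific to the RUNX1 shRNA. RUNX2 and RUNX3 were likewise lower in all 4 pairs for their own shRNAs, RUNX3 by only -0.05 between shRUNX1+shRUNX3 and shRUNX1. The levels of the cluster listed for RUNX1 and LOC100506403 lay near the level filter of 3.80, and a cluster shared with another locus is a weak check of RUNX1 itself.

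**Figure D1:**
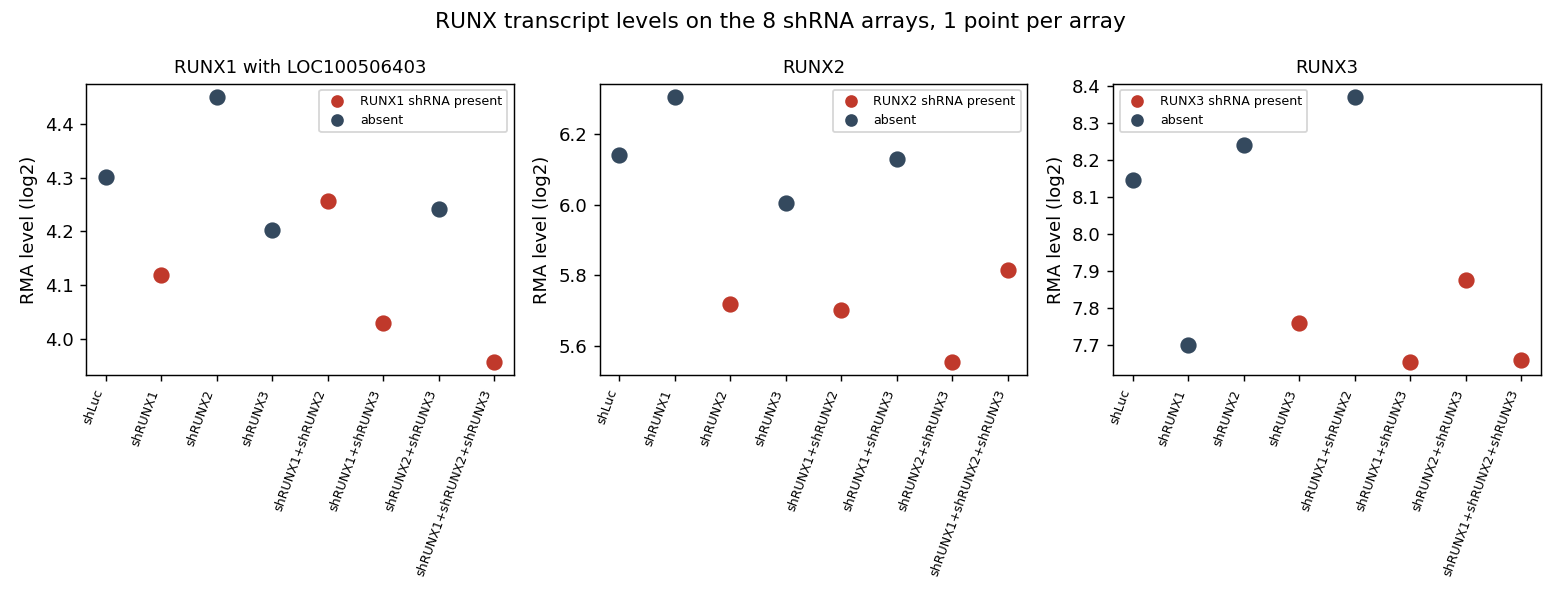
Log2 level on each of the 8 knockdown arrays (1 array per condition) of the cluster listed for RUNX1 and LOC100506403, of RUNX2 and of RUNX3, 1 panel each, with red points for arrays that carry the shRNA against that gene. The 4 red points of RUNX2 lie below the 4 others, and RUNX3 on the array labelled shRUNX1 (7.70) lies among the red points.

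In the additive limma fit, the arrays with the RUNX1 shRNA had lower levels of DNA replication and cell division genes and higher levels of some monocyte markers. All 29 S phase and E2F targets had a negative estimate, with a median of -0.61, including the G1/S regulators E2F1 (-0.83) and CCNE2 (-0.81). All 29 G2 and mitosis genes were also negative, with a median of -0.55, including the mitotic kinesins KIF20A (-0.70) and CENPE (-0.65). Adjusted over the list alone, 29 of the S phase and 27 of the mitosis genes passed, and 0 of either passed over all 12147 genes. Replication-dependent histones had a median of -0.36, with 5 of 11 past the test adjusted over the list alone, namely the linker histones H1-5 (-0.77), H1-2 (-0.55) and H1-4 (-0.36) and the core histones H2BC3 (-0.64) and H2BC14 (-0.56). Among the Fanconi and excision repair genes the median was -0.09 and 9 of 22 were lower adjusted over the list alone, such as BRIP1 (-0.74) and FANCG (-0.60). Camera gave adjusted p = 7.98e-19 for S phase, 2.03e-15 for mitosis, 0.000278 for histones and 0.00218 for both the repair genes and the MYC targets and ribosome biogenesis list (median -0.10). Each became adjusted p = 0.623 with an estimated correlation (0.925 for S phase genes).

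Several smaller groups moved with the RUNX1 shRNA. Among 14 monocyte and macrophage genes 12 had a positive estimate, with 2 past the test adjusted over the list alone, the integrin subunit ITGAX (0.96) and the lysosomal marker CD68 (0.56). The NRF2 and oxidative stress list had 17 of 19 positive estimates and 4 past the test over the list alone, malic enzyme ME1 (0.69), glutathione reductase GSR (0.40), OSGIN1 (0.28) and MT1X (0.24). The serine synthesis enzymes PHGDH (-0.98) and PSAT1 (-0.61) lay lowest in the ATF4 list, in which PHGDH and ASNS (-0.57) were lower and DDIT4 (0.57) higher adjusted over the list alone. The desaturase SCD (-0.63) and FADS2 (-0.47) lay lowest in the cholesterol and fatty acid list, and with them IDI1 (-0.27) and EBP (-0.25) were lower and TM7SF2 (0.37) higher over the list alone. MANF (-0.42) lay lowest and EDEM1 (0.46) highest in the unfolded protein response list. Camera gave adjusted p = 0.0104 for the monocyte genes, 0.00193 for NRF2, 0.025 for ATF4, 0.0154 for the lipid list and 0.0279 for the unfolded protein response, and adjusted p = 0.623 with an estimated correlation for each of these 5. CDKN1A had an estimate of -0.14, MDM2 -0.07, CBFB 0.03, BCL11A -0.14 and TRIM24 -0.02.

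No single gene passed the limma test for the RUNX1 shRNA over all genes (0 of 12147), with 2580 at an unadjusted p under 0.05. The 5 genes of smallest p were SPOPL (0.65, SE 0.0619, adjusted p = 0.0755), ACSL1 (0.62), BECN1 (0.54), UBE4A (0.45) and DMXL2 (0.55), the last 4 at adjusted p = 0.0817. Without the array labelled shRUNX1 the fit called 817 genes, 362 higher and 455 lower, among them 27 of 29 S phase genes and 27 of 29 mitosis genes, all lower. Every other array with the RUNX1 shRNA also carries another RUNX shRNA, so that fit describes combinations and not the RUNX1 shRNA alone. The stricter level filter gave 121 genes. Pairwise interaction terms gave 391, in a model that leaves only 1 residual degree of freedom. The count of 0 therefore depends on these choices.

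The cell cycle difference was uneven over the 4 arrays. Relative to shLuc, the mean of the S phase list was -0.16 on the array labelled shRUNX1, -0.42 on the array labelled shRUNX1+shRUNX2, -1.06 on shRUNX1+shRUNX3 and -0.90 on the triple knockdown. It was -0.06 with shRUNX2, 0.02 with shRUNX3 and -0.02 with shRUNX2+shRUNX3. The mean of the G2 and mitosis list was -0.10, -0.54, -1.04 and -0.88 on the same 4 arrays with the RUNX1 shRNA, and -0.21, -0.11 and -0.12 on the 3 without it. An exact permutation of the S phase mean between arrays with and without the RUNX1 shRNA gave p = 0.0286, the smallest possible, for a difference of -0.62, and 0.257 after adjustment over 81 such tests. For the mitosis list the exact permutation p was 0.114. Between arrays that differ only in the RUNX1 shRNA, both means were lower in all 4 pairs, by -0.16, -0.36, -1.08 and -0.88 for S phase and by -0.10, -0.33, -0.93 and -0.76 for mitosis (exact sign-flip permutation p = 0.125 each, the smallest possible).

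**Figure D2:**
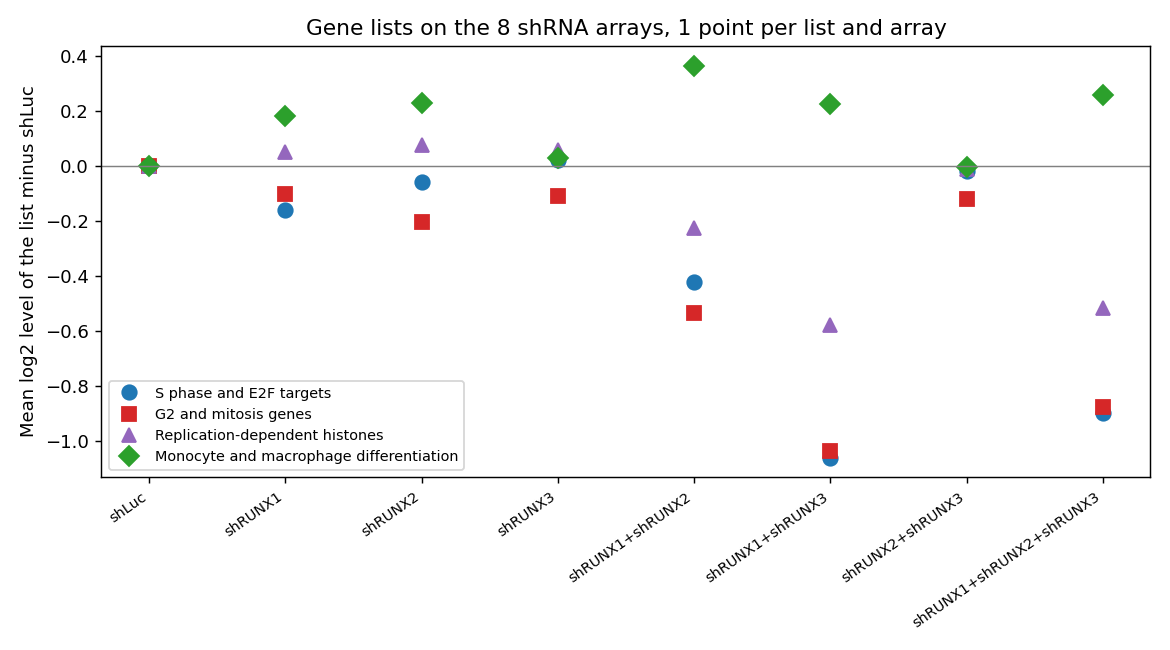
Mean log2 level of 4 gene lists on each of the 8 knockdown arrays (1 array per condition) minus the mean of the same list on the shLuc array. The S phase and G2 and mitosis lists are lowest on shRUNX1+shRUNX3 (-1.06 and -1.04) and on the triple knockdown (-0.90 and -0.88).

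With the RUNX2 shRNA, the most significant gene was RUNX2 itself, and interferon-stimulated genes lay slightly higher. RUNX2 had an estimate of -0.45 (SE 0.0663, adjusted p = 0.965), and it passed adjusted over the RUNX and CBF list alone (adjusted p = 0.0012). It was followed by ADA2 (0.46), IGHV3-15 (0.43), SLC25A12 (0.37) and PRSS36 (0.39), none past the test. Of 20 interferon-stimulated genes 18 had a positive estimate, with a median of 0.10, such as IFI6 (0.39) and SAMD9L (0.33). All 29 G2 and mitosis genes were negative, with a median of -0.12, and CDC25C (-0.37) lay lowest. Between arrays that differ only in the RUNX2 shRNA, however, the mitosis mean differed by -0.21, -0.43, -0.01 and 0.16 (exact sign-flip permutation p = 0.375). In the monocyte list 12 of 14 were positive, such as ITGAX (0.29) and S100A8 (0.28). Camera gave adjusted p = 0.000212, 0.00204 and 0.0212 for these 3 lists in that order, and adjusted p = 0.884 with an estimated correlation for each. Adjusted over the list alone, 0 members of these 3 lists passed, and limma called 0 genes over all 12147, with 593 at an unadjusted p under 0.05. Among the other fixed genes RUNX3 had an estimate of 0.22, CBFB -0.07, MDM2 0.15, CDKN1A 0.01, BCL11A -0.21 and TRIM24 -0.07.

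With the RUNX3 shRNA, cell cycle genes again lay lower and the calprotectin genes S100A8 and S100A9 lay lower. The median estimate was -0.31 over 29 S phase genes and -0.34 over 29 G2 and mitosis genes, all 58 negative, with CCNE2 (-0.65), GINS1 (-0.55), TOP2A (-0.46) and CENPF (-0.44) lowest. Without the RUNX1 shRNA the S phase mean was near shLuc on shRUNX3 (0.02) and on shRUNX2+shRUNX3 (-0.02), so the low estimates come from the 2 arrays that also carry the RUNX1 shRNA. Histones had a median of -0.24, led by H1-5 (-0.50), and Fanconi and excision repair genes had -0.15. Camera gave adjusted p = 7.83e-12 for S phase and for mitosis, 0.000331 for histones and for the repair genes, 0.0343 for cholesterol and fatty acid synthesis (ACAT2 -0.32, SQLE -0.27) and 0.0452 for housekeeping genes (PGK1 -0.29). With an estimated correlation the adjusted p was 0.67 for S phase, mitosis and histones, 0.742 for the lipid list and 0.563 for the repair and housekeeping lists. S100A9 (-0.53) and S100A8 (-0.43), which are abundant in mature myeloid cells, were the 2 monocyte genes lower adjusted over the list alone. RUNX3 itself had an estimate of -0.38 (adjusted p = 0.426). Limma called 0 genes, with 1141 at an unadjusted p under 0.05. The smallest p belonged to PEAK3 (0.97), SLC39A9 (-0.70), SPOPL (0.48), ACSL1 (0.50) and FCN2 (-0.46), all at adjusted p = 0.206. RUNX2 had an estimate of -0.09, CBFB -0.10, MDM2 -0.05, CDKN1A -0.25, BCL11A 0.01 and TRIM24 0.02.

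Over the number of RUNX genes targeted, VAPA rose and cell cycle genes had negative slopes, although their list means did not fall at every added target. VAPA, a membrane protein of the endoplasmic reticulum, rose by 0.55 per gene targeted (SE 0.0542, limma adjusted p = 0.0386) and was the only gene of 12147 past the test, with 2322 at an unadjusted p under 0.05. The slope had a median of -0.34 over the G2 and mitosis genes and -0.33 over the S phase genes, and 27 of 29 in each list were lower adjusted over the list alone. CCNE2 (-0.48), E2F1 (-0.48), KIF20A (-0.44) and CENPE (-0.41) had the steepest slopes there. The histones H2BC3 (-0.42) and H1-5 (-0.40) had the steepest slopes among histones, of which H2BC3, H2BC14, H1-2 and H1-4 were lower adjusted over the list alone. Of 22 Fanconi and excision repair genes 8 were lower and 1, FANCF (0.15), was higher over the list alone. PHGDH (-0.54) and PSAT1 (-0.36) again lay lowest in the ATF4 list. Camera gave adjusted p = 3.47e-17 for mitosis, 1.7e-15 for S phase, 7.27e-05 for histones, 0.00163 for the repair genes, 0.00223 for the lipid list, 0.023 for ATF4 and 0.0323 for MYC targets. With an estimated correlation the adjusted p was 0.525 for MYC targets and 0.506 for the other 6. RUNX2 had a slope of -0.13, RUNX3 -0.11, CBFB -0.05, MDM2 0.01, CDKN1A -0.13, BCL11A -0.11 and TRIM24 -0.03. The VAPA call ended without the level filter (adjusted p = 0.0568) and without any of shLuc, shRUNX1, shRUNX2, shRUNX3, shRUNX1+shRUNX2 or the triple knockdown. Without shRUNX2+shRUNX3 the fit called 234 genes, and the number of targets cannot be told apart from the number of shRNA vectors.

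The triple knockdown lay lower than shLuc in cell cycle genes, and 2 of 14 monocyte genes, ITGAX and CD68, lay at least 2-fold higher. The 10 highest genes were the serotonin receptor HTR2B (1.79), MANSC1 (1.78), SEMA6B (1.65), the ectoenzyme CD38 (1.65), VAPA (1.56), SORL1 (1.54), SERPINF1 (1.54), SMIM14 (1.51), LILRA2 and IGSF6. The 10 lowest were ANKFN1 (-3.49), the folate enzyme ALDH1L2 (-2.18), the E2F family members E2F8 (-1.62) and E2F7 (-1.57), ARSK (-1.50), PHGDH (-1.46), CDKN3 (-1.46), TERF1 (-1.43), TICRR (-1.41) and CCNF (-1.41). All 29 S phase genes lay lower, with a median of -0.89 and 8 at least 2-fold lower, such as the replication factors GINS1 (-1.31) and GINS2 (-1.26). All 29 G2 and mitosis genes lay lower, with a median of -0.91 and 9 at least 2-fold lower, such as CCNB2 (-1.26) and KIF20A (-1.22). Histones had a median of -0.52 (H1-5 -1.06, H2BC3 -1.05) and Fanconi and excision repair genes -0.37 (BRIP1 -1.07, BRCA1 -0.99). None of the 10000 matched random lists had a lower median than any of these 4 lists, which is the 0th percentile.

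Cholesterol and fatty acid genes lay at the 0.02nd percentile in the triple knockdown (median -0.24, SCD -1.01, ACAT2 -0.86). Immediate early genes lay at the 0.51st percentile (median -0.14, and -0.05 without the level filter), although FOS was at 0.81. The core-binding factor myeloid targets lay at the 98.7th percentile (median 0.12, mean 0.04), with the granulocyte colony-stimulating factor receptor CSF3R at 0.74 but CCND3 at -0.92 and NFE2 at -0.60. The monocyte list lay at the 98.3rd (median 0.17, ITGAX 1.36, CD68 1.04). RUNX and CBF genes lay at the 1.33rd percentile, with RUNX2 at -0.33, RUNX3 at -0.49 and CBFB at -0.10. RUNX2 and RUNX3 are themselves targets of the shRNAs on this array, and the median of the 5 tested members is the RUNX2 value. This percentile therefore partly restates the knockdown. Housekeeping genes, too, lay at a low percentile, 2.46, with a median of -0.20. MDM2 differed by -0.11, CDKN1A by -0.38, BCL11A by -0.32 and TRIM24 by -0.12. In all, 174 genes differed at least 2-fold, 68 higher and 106 lower, with no replicate check. Against shLuc the counts were 24 for shRUNX1, 22 for shRUNX2, 27 for shRUNX3, 44 for shRUNX1+shRUNX2, 240 for shRUNX1+shRUNX3 and 14 for shRUNX2+shRUNX3. Differences simulated from the residual spread alone gave 12.4 such genes on average and 21 at most, and the fold threshold sets the count (957 at 1.5-fold and 9 at 3-fold).

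After 6 hours with Chb-M', CDKN1A rose, very long genes fell, and mitosis genes lay lower while S phase genes lay higher. The cyclin-dependent kinase inhibitor CDKN1A rose by 1.44 (SE 0.209, adjusted p = 0.047 by the pooled-spread limma test), as did the stress response gene GADD45A (0.95). The CDKN1A call ended without any 1 knockdown array (adjusted p from 0.0562 to 0.102 in the same test), and without shLuc no gene passed. SESN2 (1.40), PLK2 (1.37), EDA2R (1.12) and MDM2 (0.82, adjusted p = 0.116) lay higher without passing the test. Among the genes that fell were CSMD3 (-1.79), ADGRL3 (-1.65), ARHGAP32 (-1.59), FER (-1.52), CDKAL1 (-1.49), GPHN (-1.44), VPS13B (-1.33) and UTRN (-1.33), with adjusted p from 0.0247 to 0.0486. Their spans in the annotation run from 315 kb for ARHGAP32 to 1227 kb for GPHN, while the median over all protein-coding genes tested was 27.6 kb.

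Mitosis genes all lay lower with Chb-M' (29 of 29, median -0.58, 0th percentile), led by CENPE (-1.77) and DLGAP5 (-1.19), and CENPE passed adjusted over the list alone. S phase genes mostly lay higher (27 of 29, median 0.38, 100th percentile), led by CCNE2 (1.02) and E2F2 (0.86), and none passed. Histones lay lower (median -0.41, 0th percentile, H2BC3 -1.25). Immediate early genes lay higher (median 0.30, 100th percentile), with 7 of 24 past the test adjusted over the list alone, including FOS (1.56), FOSB (1.36), JUN (1.05) and NR4A2 (0.95). Short-lived regulatory transcripts lay at the 99.8th percentile, and SERTAD1 (1.06) rose past the test over all genes. NF-kB and inflammatory genes lay at the 99.9th percentile (median 0.24, CD83 0.48), with a median of 0.10 without the level filter. The KMT2A-fusion programme lay lower (median -0.28, 0th percentile), with the chromatin remodeller subunit ARID1B (-0.63) and JMJD1C (-0.51) lowest, and these 2, PBX3 (-0.45) and CPEB2 (-0.34) lower adjusted over the list alone. The random lists were not matched on genomic span, and the longest 10% of genes had a median of -0.31 with Chb-M'. Gene length was therefore not separated from the fall of this list. It was also not separated from the rise of the short-lived transcripts, as the shortest 10% of genes had a median of 0.09. RUNX2 lay at -0.31, RUNX3 at 0.31, CBFB at -0.17, BCL11A at -0.10 and TRIM24 at -0.27, none past the test. The other highest genes included TRAJ59 (1.82), KRTAP10-9 (1.51), TNFSF9 (1.19), SH3GL1P2 (1.18) and KCNK15 (1.11), and the other lowest were MAP2K6 (-1.52), HBQ1 (-1.47) and KIF14 (-1.37).

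In all, 106 genes differed at least 2-fold from DMSO with Chb-M', 38 higher and 68 lower, and 74 passed the pooled-spread test, 16 higher and 58 lower. Of 55 protein-coding genes that fell, 51 were among the 10% of genes with the longest genomic span, and their median span was 373 kb. The 13 protein-coding genes that rose had a median span of 10.3 kb, and 0 were among those longest genes. The pooled-spread count was 0 without any 1 of shLuc, shRUNX2, shRUNX3, shRUNX1+shRUNX2, shRUNX2+shRUNX3 or the triple knockdown, 5 without shRUNX1+shRUNX3 and 7 without the level filter. Without the array labelled shRUNX1 it was 77. The CDKN1A call ended without each knockdown array in turn (adjusted p from 0.0562 to 0.102) and without the level filter (adjusted p = 0.0651).

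With Chb-50 at the same dose and time, the S phase, mitosis and histone lists stood apart in the same directions as with Chb-M', with smaller medians. CDKN1A (1.23) and PLK2 (1.17) lay at least 2-fold higher, and MDM2 lay 0.71 higher. Mitosis genes lay at the 0th percentile (29 of 29 lower, median -0.39), with CENPE (-1.15) and KIF20A (-0.91) lowest. S phase genes lay at the 100th (median 0.23, CCNE2 0.72, E2F2 0.67). Histones lay at the 0.01st (median -0.24), the KMT2A-fusion programme at the 1.17th (median -0.10, ARID1B -0.48), interferon-stimulated genes at the 1.85th (median -0.12, SAMD9L -0.74) and short-lived regulatory transcripts at the 99.5th. Gene length was not separated from the place of the KMT2A-fusion and short-lived lists, and the longest 10% of genes had a median of -0.19 with Chb-50. Immediate early genes lay at the 92.5th percentile (median 0.06). Long genes were among the lowest, with GPHN (-1.13), CSMD3 (-1.12), ADGRL3 (-1.04), ARHGAP42 (-1.04) and LRBA (-1.03), beside the kinesins KIF14 (-1.10) and KIF18A (-1.02). The other lowest were TRAV1-2 (-1.44), ANKRD20A12P (-1.13), TRGV2 (-1.11) and SNURFL (-0.99). The other highest included TSPYL6 (1.04), LYNX1 (1.04) and SLC25A53 (1.03). RUNX2 differed by -0.23, RUNX3 by 0.22, CBFB by -0.15, BCL11A by -0.03 and TRIM24 by -0.01. In all, 36 genes differed at least 2-fold, 17 higher and 19 lower, of which 14 were protein-coding, against up to 13 protein-coding genes in the simulated differences. The pooled-spread limma test called 0 genes, with 1114 at an unadjusted p under 0.05.

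Set against each other at 1 µM and 6 hours, the single arrays of the compounds stood apart in immediate early genes, and by percentile in histones and other lists. FOSB lay 1.62 higher with Chb-M' than with Chb-50 (95% interval 0.98 to 2.25, adjusted p = 0.372), FOS 1.31 higher (0.52 to 2.11) and EGR1 1.19 higher (0.35 to 2.03). Against DMSO, Chb-50 gave 0.25 for FOS, -0.26 for FOSB and -0.29 for EGR1. These genes also varied between the knockdown arrays, which had no compound. There FOS read 7.12 to 8.385, around the 8.007 with Chb-M' and above DMSO (6.447) and Chb-50 (6.693). EGR1 read 6.184 to 7.033 there, against 7.065 with Chb-M'. FOSB read 4.848 to 5.526 there, below the 6.205 with Chb-M'. Immediate early genes had a median difference of 0.27 between the compounds (100th percentile, 22 of 24 higher; 0.20 without the level filter), and FOS, FOSB, JUN (0.78) and NR4A2 (0.86) passed adjusted over the list alone. S phase genes had a median of 0.16 (100th percentile), mitosis genes -0.16 (0th), histones -0.26 (0.01st) and the KMT2A-fusion programme -0.14 (0.03rd). None of their members passed adjusted over the list alone. Gene length was not separated from the KMT2A-fusion difference, as the longest 10% of genes had a median of -0.12 between the compounds. SESN2 lay 0.63 higher with Chb-M' (-0.03 to 1.29), ARHGAP32 differed by -0.77 (-1.11 to -0.43), FER by -0.62 (-1.01 to -0.24) and CSMD3 by -0.67 (-1.08 to -0.26). LYNX1, which read the same 4.17 on the DMSO and Chb-M' arrays, differed by -1.04 (-1.30 to -0.77, adjusted p = 0.184). For CDKN1A the difference was 0.22 (-0.28 to 0.71), for MDM2 0.10 (-0.33 to 0.54), for RUNX2 -0.08 (-0.39 to 0.23), for RUNX3 0.09 (-0.43 to 0.60), for CBFB -0.02 (-0.29 to 0.25), for BCL11A -0.07 (-0.58 to 0.44) and for TRIM24 -0.26 (-0.51 to -0.01), and these widths do not show that the compounds act alike. By size, 24 genes differed at least 2-fold, 15 higher and 9 lower with Chb-M', close to the simulated maximum of 21. The pooled-spread limma test of the difference called 0 genes, with 869 at an unadjusted p under 0.05. With the mean over clusters FOSB differed by 0.99.

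**Figure D3:**
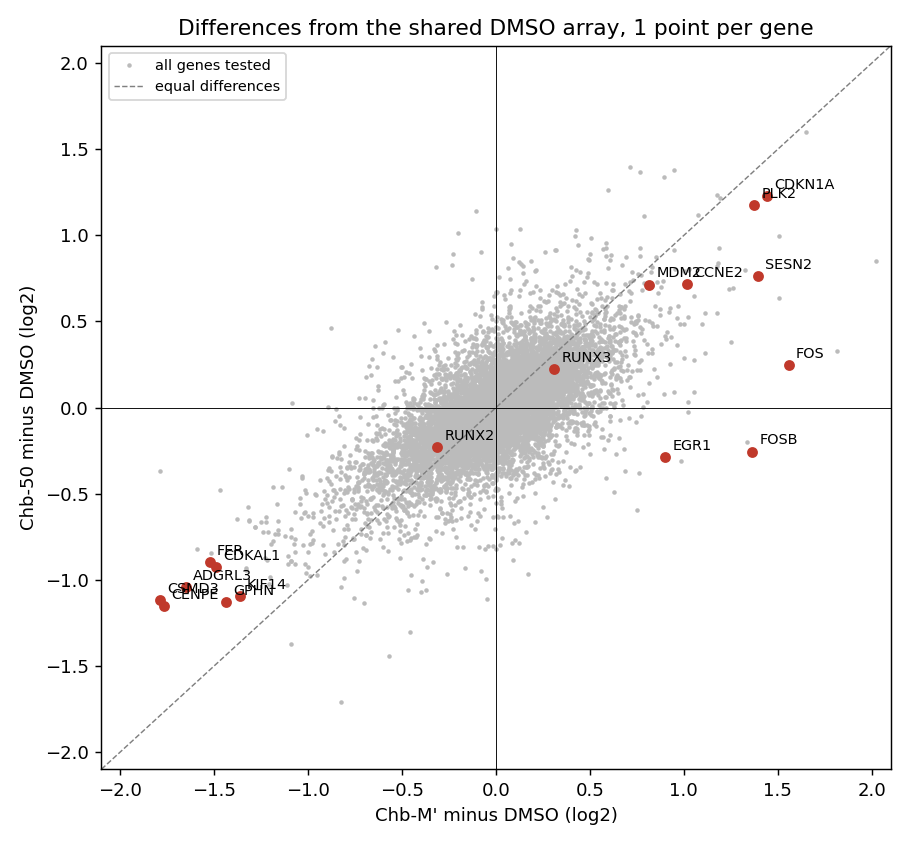
Log2 difference from DMSO after 6 hours at 1 µM with Chb-M' (horizontal axis) and with Chb-50 (vertical axis), 1 point per gene tested and 1 array per condition, with named genes labelled. CDKN1A (1.44 and 1.23) and GPHN (-1.44 and -1.13) lie far out on both axes, while FOS (1.56 and 0.25) and FOSB (1.36 and -0.26) lie far out with Chb-M' alone.

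The compounds' differences from DMSO covaried by more than the shared DMSO array gave in simulation, and neither correlated with the triple knockdown across all genes. Across 12147 genes the differences from DMSO had a Pearson r of 0.669 and a Spearman rho of 0.636, against a simulated r of 0.499 from the shared DMSO array alone. The covariance was 0.0477 against a simulated 0.0183, a difference of 0.0295. The simulation gave the DMSO array the residual spread of the knockdown arrays. A more variable DMSO array would also raise the covariance, so the excess cannot be assigned to the compounds alone. At 2-fold, 6 genes were higher and 8 lower with both, where independent lists would share 0.0532 and 0.106, and part of this excess may come from the shared control array. With the triple knockdown, which has its own control, the Pearson r across genes was 0.0139 for Chb-M' and 0.0179 for Chb-50. At 2-fold, 5 genes were lower in both the triple knockdown and Chb-M' (0.593 expected of independent lists) and 3 in both the triple knockdown and Chb-50 (0.166 expected), while 1 and 0 were higher in both (0.213 and 0.0952 expected). S phase genes had a median of -0.89 in the triple knockdown and 0.38 with Chb-M'. Mitosis genes lay lower in both (-0.91 and -0.58). The triple knockdown array followed 24 hours with doxycycline, and the compound arrays followed 6 hours of exposure. Against shLuc, RUNX2 differed by only -0.33 and RUNX3 by -0.49 on the triple knockdown array, and RUNX1 had no cluster of its own. With unlike times and partial knockdown, these comparisons cannot tell whether the compounds act like a loss of RUNX genes.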

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

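All tests of explanations in this part were chosen only after the result was seen. For 5 gene lists a test of the difference itself found that the RUNX1 shRNA effect differed with and without the RUNX3 shRNA, which set them apart for a closer look, although with an estimated correlation the adjusted p was 0.914 for each. With the RUNX3 shRNA, the RUNX1 shRNA effect was lower by a median of -0.704 over S phase and E2F targets (camera adjusted p = 3e-24 at the preset correlation) and -0.673 over G2 and mitosis genes (1.41e-15). It was lower by -0.431 over replication-dependent histones (1.29e-05), by -0.162 over MYC targets and ribosome biogenesis genes (0.00103) and by -0.151 over ATF4 and integrated stress response genes (0.0193). Adjusted over the list alone, 28 S phase genes, 19 mitosis genes and 4 histones passed the limma test of the interaction, and over all genes 0 passed, with 1544 at an unadjusted p under 0.05. The RUNX1 and RUNX2 pair had 285 such genes and the RUNX2 and RUNX3 pair 572, with 0 past the test in each.

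The array labelled shRUNX1 stayed near shLuc in cell cycle genes (-0.16 for the S phase mean) while shRUNX1+shRUNX3 and the triple knockdown did not (-1.06 and -0.90). A weaker RUNX1 knockdown on that array is a possible technical explanation and stays open, since the cluster listed for RUNX1 and LOC100506403 read 4.12 there and was lower than on the matched array (-0.18), but it was also lower in all 4 pairs that differ only in the RUNX3 shRNA (mean -0.17). A wrong label on that array was not tested and would change what every value for shRUNX1 means. The 817 genes were called without that array, so a wrong label on it alone would not change them. RUNX3 (7.70) was about as low there as on the arrays with the RUNX3 shRNA. ANKFN1 read 8.33 there and 4.23 to 4.63 on those arrays. It also read 5.23 on shRUNX2 and 4.92 on DMSO, which carry no RUNX3 shRNA, so ANKFN1 is no marker of that shRNA. These single genes do not settle the label. A combined effect of losing RUNX1 and RUNX3 is a possible biological explanation, and the smallest adjusted p of the interaction over single genes was 0.249, so this test cannot tell either. A difference between single cultures could give the same picture, and more arrays per condition would be needed to separate them.

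Splits of the 8 arrays into 4 and 4 were also refitted with each shRNA term replaced in turn. For the RUNX1 shRNA, 33 of the 33 splits gave at least as many genes past the test as the real split (0), and the highest other count was 1. For the RUNX2 and RUNX3 shRNAs it was again 33 of the 33 splits, with real counts of 0 and highest other counts of 0. No split can give fewer than 0 genes, so these counts were fixed by the real count of 0 and decide nothing about chance.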

How the results depend on the processing

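Counts of genes past a threshold depended on the settings. Among the main results 111 alternatives gave the same verdict, 39 moved and 1 became stronger. Among genes named in the fits 1649 were the same, 27 became stronger and 72 weaker, none reversed. All 9 list medians that moved did so without the level filter, and 4 of them changed sign: NF-kB genes (-0.05) and lymphoid markers (-0.02) in the triple knockdown, and erythroid markers with Chb-M' (-0.13) and between the compounds (-0.10). For the 2-fold counts the thresholds of 1.5-fold and 3-fold gave 957 and 9 (triple knockdown), 663 and 9 (Chb-M'), 409 and 2 (Chb-50) and 281 and 2 (Chb-M' against Chb-50), as the threshold itself sets. The stricter level filter gave 61, 10 and 6 for Chb-M', Chb-50 and their difference, no filter gave 62 and 53 for the latter, and protein-coding genes alone, chosen after seeing the data, gave 14 and 5. The correlation of the compounds was 0.605 without the filter. For the RUNX1 shRNA, the stricter filter gave 121 genes, a mean-variance trend with robust eBayes 65 and an adjusted p under 0.1 gave 375. Pairwise interactions gave 391, with only 1 residual degree of freedom. The cause of these changes was not tested. Without the level filter the number of targets gave 0 genes and the pooled-spread test of Chb-M' gave 7, as more genes are tested. With each array centred on its median the RUNX1 and LOC100506403 cluster differed by -0.23 (exact permutation p = 0.0286, and 0.129 adjusted over the 9 tests).

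Leaving out each array in turn gave 0 to 817 genes for the RUNX1 shRNA, 0 to 0 for RUNX2, 0 to 1 for RUNX3, 0 to 234 for the number of targets, 0 to 77 for Chb-M' and 0 to 0 for Chb-50 and for the difference of the compounds. The 817 came without the array labelled shRUNX1, and SMIM14 (without shRUNX1+shRUNX3), CD38 (without shRUNX2) and, for RUNX3, ANKFN1 (without shRUNX2) were single calls. The 234 came without shRUNX2+shRUNX3. The VAPA call ended without shLuc, shRUNX1, shRUNX2, shRUNX3, shRUNX1+shRUNX2 or the triple knockdown, with adjusted p from 0.0842 to 0.537. For these changes the cause was not tested. No paired analysis was possible because the groups share only replicate number 1, which links no cultures; arrays that differ in 1 shRNA were compared within pairs instead, for the RUNX levels and cell cycle lists, chosen after seeing the data. Taking each transcript cluster of RUNX2 or RUNX3 gave no further value, since each has 1 cluster. Without signal over background, small differences at low levels cannot be told from noise.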

Other observations

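Long genes lay lower with both compounds, with little trend among the shortest 40% of genes and most of the fall among the longest 30%. Over 10572 protein-coding genes the rank correlation of the log2 difference with genomic span was -0.408 for Chb-M' and -0.309 for Chb-50. The shortest 10% of genes (median span 2.75 kb) had a median of 0.09 with Chb-M' and 0.06 with Chb-50, and the longest 10% (204 kb) had -0.31 and -0.19, with 84.8% and 81.3% of genes lower. After subtracting the median of each span group, mitosis genes kept a median of -0.60 with Chb-M' and -0.43 with Chb-50. Named beyond the rule, chosen after their values were seen, were the repair genes XRCC4 (-1.09) and MSH3 (-1.03), DPYD (-1.10) and FOXP2 (-1.28), which fell with Chb-M', and SNAI1 (1.10) and AMER1 (0.83), which rose. SERTAD1 and the values of FOS, FOSB and EGR1 with Chb-50 in the report, were also chosen after they were seen.

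ANKFN1, the lowest gene of the triple knockdown, split the knockdown arrays by more than their labels. It read 7.91 on shLuc, 8.33 on the array labelled shRUNX1 and 7.62 on the array labelled shRUNX1+shRUNX2. It read 5.23 on shRUNX2, 4.61 on shRUNX3, 4.63 on shRUNX1+shRUNX3, 4.23 on shRUNX2+shRUNX3 and 4.42 on the triple knockdown. On the DMSO, Chb-M' and Chb-50 arrays it read 4.92, 4.17 and 3.97. RUNX1-IT1, a transcript from within the RUNX1 locus, read 6.28, 6.77, 6.75 and 6.71 on the arrays labelled shRUNX1, shRUNX1+shRUNX2, shRUNX1+shRUNX3 and the triple knockdown, all above the 4 arrays without the RUNX1 shRNA (6.27 on shLuc, 5.88 on shRUNX2, 5.61 on shRUNX3 and 6.01 on shRUNX2+shRUNX3). It was chosen after its values were seen, and the gap between shLuc and shRUNX1 was small. The first principal component of the 8 knockdown arrays held 46.6% of the variance and placed shRUNX1+shRUNX3 (0.601) and the triple knockdown (0.509) farthest from shLuc (-0.347).

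The lists not described above lay mostly inside the random range. In the triple knockdown interferon-stimulated genes lay at the 97.3rd percentile, ATF4 genes at the 3.14th, unfolded protein response genes at the 2.5th, glycolysis genes at the 95.4th and MYC targets at the 10.4th. Stem cell genes lay at the 47.9th, heat shock genes at the 17.8th, apoptosis genes at the 78th, erythroid genes at the 32.7th and lymphoid genes at the 85.4th. With Chb-M' ATF4 genes at the 96.1st (GADD45A and SESN2 past the test adjusted over the list alone), interferon-stimulated genes at the 9.87th, monocyte genes at the 88.8th, Fanconi and excision repair genes at the 20.9th, erythroid genes at the 60.4th and lymphoid genes at the 83.1st. Epithelial and stromal markers had 3 tested members and were not tested.

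All tests of the long-gene pattern were chosen only after the result was seen. A loss of transcript that grows with gene length is a hypothesis for both compounds, and the weaker of the correlations, -0.309 with Chb-50, is the pattern that prompted it and no separate test of it. Blocked elongation on alkylated DNA could produce such a trend, which these arrays do not measure. Lower levels of long genes might mimic it, but within 3 groups of equal size by level the longest 20% of genes minus the shortest 20% gave -0.10 or lower with either compound, which excludes level alone. A trend as strong on every array was excluded, since the lowest correlation of the knockdown differences was -0.102, with shRUNX3. That value still exceeded in size the largest found with shuffled spans (0.0263), so a weaker trend between knockdown arrays is not excluded. An odd DMSO array was excluded as the only source of the Chb-M' trend. The difference between the compounds, which leaves DMSO out, had a correlation of -0.246. That difference cannot tell whether the Chb-50 trend came from the DMSO array. DMSO minus shLuc had a correlation of -0.0049, inside the largest size found with shuffled spans (0.0255). The DMSO array thus showed no length trend against shLuc, a single array from cells kept under other conditions.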
